A study of Mus musculus with 4 samples.

How the data were processed

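Single-cell RNA-seq of immune cells had been deposited for 4 droplet libraries (10x Genomics 3′ v3 chemistry), made from bone marrow and peripheral blood of mice with B-cell acute lymphoblastic leukaemia (B-ALL) and of healthy recipient controls. Each library pooled cells of 2 mice, marked before pooling by antibodies that carry a sequence tag: BALL8 and BALL9 for B-ALL, CON1 and CON2 for control. Per the labels, all mice were female and 10 weeks old, and the B-ALL mice were moribund. Marrow was flushed from tibias and femurs, red cells were lysed, and viable cells were sorted. The B-ALL samples were mixed after the sort as 1 part blasts (GFP+CD19+), 8 parts GFP-negative CD45+ cells without Ly-6G, and 1 part GFP-negative CD45+ cells with Ly-6G, the granulocyte marker. The control samples were mixed 8 to 1 from the last 2 kinds of cells, without a blast part. The labels name the same gate for both control sorts, but 2 gates for the mix. The mix therefore bears on the shares of blasts and of cells with Ly-6G, so neutrophil-like and pro/pre-B-like shares were not among the main tests. It did not fix these shares. Neutrophil-like cells made up 43.6% ± 3.5 of all cells in B-ALL marrow and 24.9% ± 3.7 in control marrow (SD, n = 2 mice). Pro/pre-B-like cells made up 13.7% ± 1.7 and 23.3% ± 0.5 there. In blood, neutrophil-like cells made up 10.9% ± 3.4 in B-ALL and 6.26% ± 5.84 in control.

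Each deposited matrix holds UMI counts (unique molecular identifiers, 1 per captured RNA molecule) for 31053 genes and every possible barcode. Per the file headers, the matrices are in format version 2 of software version 3.0.0. Cell Ranger, bcl2fastq and Seurat are named in the submitters' processing notes without versions, with the mouse build mm10/GRCm38. A further table of raw counts per gene and cell, deposited by the authors, holds 27162 cells and 17673 genes, and was used for the main results. The filters behind it are not given in the sources used here. In its values, each cell had under 10% of counts from mitochondrial genes. Tag counts per barcode, deposited separately, assigned each cell to the mouse with more tag UMIs. The ratio of the tags was under 4 in 966 of the 5351 marrow cells of BALL9 (18.1%), and in 0.05% to 1.1% of cells of each other mouse and tissue. The authors' normalized table, a natural log of scaled counts, was not used, since the tests need counts.

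Cells were scaled to 10000 counts and log-transformed, and 2000 variable genes gave 40 principal components (scanpy 1.11.5). A graph of 20 neighbours was clustered by the Leiden method at resolution 1 (leidenalg 0.10.2, seed 1), which gave 39 clusters. Clusters were named from 18 marker lists fixed before the data were examined. The name with the highest mean log2 enrichment of its markers was taken where it reached 1, led the next name by 0.5, and rested on at least 3 markers detected in 10% of cells. These score limits were set after the data were seen. The names cover 13 classes, each called "X-like". Cluster 6 lay between classical monocyte-like and granulocyte-monocyte progenitor-like cells and cluster 27 between NK-like and T-like cells, so each was kept as an intermediate. Cluster 32 (136 cells, low UMI counts) and cluster 38 (40 cells, mostly predicted doublets) stayed unnamed. Scrublet's method, run per library, marked 595 cells (2.19%) as doublets, which were kept in the main results and removed in an alternative.

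Raw counts were summed per class, mouse and tissue, and 52 sums of at least 20 cells were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05 were used, and all sums of a class shared 1 estimate of the spread. The mouse is the replicate, with n = 2 in each group. Disease and library coincide within a tissue, because both mice of a group were processed in the same library. The p-values measure the spread between mice inside libraries and cannot separate disease from library. Classical monocyte-like cells of blood could not be compared, since control blood held 15 and 10 of them. Shares of cell classes were tested with the same method on cell numbers, with neutrophil-like and pro/pre-B-like cells left out of the denominator, in 26 tests and 13 tests of the difference between tissues. Values of single quantities were compared with exact permutation tests, whose smallest two-sided p with 2 mice against 2 is 0.333.

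The test of the difference between tissues set the disease effect in blood against that in marrow. Gene lists, 33 in all and fixed before the data were examined like the designs, the alternatives not named as added and the rule for naming genes, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. With an estimated correlation, 0 of the 537 list tests passed (smallest adjusted p = 0.111, and 69 had an unadjusted p under 0.05), against 219 with the preset one, so every list result below rests on the preset value. Members of a list are counted as called over all genes tested, and again with p-values adjusted over the list alone. The rule for named genes took called genes with a mean log2 CPM (counts scaled to a common library size) of at least 5 whose mice did not overlap between groups. It took the 8 largest changes each way in monocyte-like and pro/pre-B-like cells and the 3 largest each way in the other classes. Receptor segments, mitochondrial genes, unnamed gene models and markers of other cell types were left out of this ranking. Up to 4 members of lists that passed were added. Genes outside these rules are described as such. CPM values are given as mean ± SD over 2 mice, and log2 fold changes ± standard error. A gene with 0 counts in 1 group is given as at least N-fold higher, against a floor of 3 counts over the group. With 1 to 3 counts a ratio of counts is given with its 95% Poisson interval. Floors and intervals cover counting error only. Gene spans come from the GENCODE annotation of GRCm38, which held 30934 of the 31053 gene identifiers. The counts are sums over whole genes.

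Bone marrow and blood with the same mouse name came from the same animal, by the titles, so the names pair samples across tissues. Deviations of the 2 mice from their group mean correlated across genes between the tissues by 0.62 in non-classical monocyte-like, 0.65 in pro/pre-B-like, 0.40 in classical monocyte-like, 0.26 in NK-like, 0.22 in neutrophil-like, 0.13 in T-like and 0.12 in mature B-like cells of B-ALL, and by −0.04 to 0.13 in control classes, a range that holds the last 2 values of B-ALL. In an alternative, the mouse entered the tissue and interaction contrasts of genes and gene lists as a block. The tests of shares had no such alternative and did not pair the tissues.

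The alternatives chosen before the data were examined were DESeq2 1.42.0, median-of-ratios (RLE) size factors, no filter on low counts, equal cell numbers per mouse, a fit on 1 tissue, cells rebuilt from the matrices, clusters at resolutions 0.5 and 2, cells thinned to 2000 UMIs, doublets removed, all cells as the denominator, genes of other cell types left out, and each mouse left out in turn. With 1 mouse left out, the lone mouse of that group is assumed to vary like the others. Added after the data were seen were 5 more: cells with a tag ratio of at least 4, T-like cells without cluster 36, no proliferation genes, free RNA subtracted, and clustering without the 4429 genes called between B-ALL and control. The last gave 28 clusters and the same class for 81.9% of cells. Rebuilt cells needed at least 30 tag UMIs, 500 genes and under 10% mitochondrial counts, and the thinning left out 884 cells.

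The steps were tested on simulated data with 200 genes changed in counts drawn from the real means and library sizes. In non-classical monocyte-like cells of blood (6101 genes), 86.4% of genes changed 4-fold, 34.3% of those changed 2-fold and 1.49% of those changed 1.5-fold were recovered. In pro/pre-B-like cells of B-ALL against control (11267 genes) these shares were 60.6%, 8.96% and 0%. False calls made up from 1.85% of calls (neutrophil-like, blood) to 17.0% (mature B-like, difference between tissues), above the nominal 5% in 16 of the 18 gene comparisons, and no called gene had the wrong sign. Depth per library was 112601463 UMIs in B-ALL marrow, 62509733 in B-ALL blood, 95910880 in control marrow and 20262413 in control blood.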

Results

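Gene expression was measured in single immune cells from bone marrow and blood of mice with B-ALL, a leukaemia of B cell precursors, and of control mice, to describe the immune cells that surround the leukaemia. The 4 libraries held 27162 cells and 291284489 UMIs. B-ALL marrow gave 9575 cells with a median of 10021 UMIs and 2840 genes per cell, and B-ALL blood 7616 cells with 6844.5 UMIs and 2443 genes. Control marrow gave 7476 cells with 8645 UMIs and 2579 genes, and control blood 2495 cells with 6257 UMIs and 2164 genes. Each library held 2 mice: 4224 cells of BALL8 and 5351 of BALL9 in marrow and 3925 and 3691 in blood, against 3344 of CON1 and 4132 of CON2 in marrow and 1040 and 1455 in blood. Both mice of a group shared a library within each tissue, so a difference between B-ALL and control is also a difference between libraries. The libraries differed in mitochondrial counts over all cells. Their median share per cell was 2.65% and 2.83% in B-ALL blood (BALL8 and BALL9), against 5.38% and 5.56% in control blood (CON1 and CON2). In marrow it was 3.57% and 3.87%, against 5.10% and 5.36%. The cells fell into 13 classes with known markers. Of the clusters left between or outside these classes, cluster 6 held 990, 5, 309 and 0 cells of B-ALL marrow, B-ALL blood, control marrow and control blood, and cluster 27 held 62, 18, 197 and 19. Cluster 32 held 112, 4, 19 and 1, and cluster 38 held 27, 1, 12 and 0.

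The first comparison asked which immune cells differed in share between B-ALL and control. Non-classical monocyte-like cells, the patrolling monocytes of blood, made up 52.9% ± 4.9 of B-ALL blood and 4.33% ± 1.16 of control blood (SD, n = 2 mice), counted over cells that were neither neutrophil-like nor pro/pre-B-like. Their share was higher by 3.62 ± 0.37 on the log2 scale (SE, edgeR adjusted p = 0.000172). Natural killer (NK)-like cells of blood took 14.5% ± 1.0 in B-ALL and 7.02% ± 0.39 in control (log2 difference 1.05 ± 0.31, adjusted p = 0.0349). Classical monocyte-like cells took 4.08% ± 1.49 and 1.16% ± 0.64 (1.87 ± 0.50, adjusted p = 0.0296). T-like cells were lower, at 5.56% ± 1.93 against 21% ± 4.9 (−1.92 ± 0.45, adjusted p = 0.0202). Mature B-like cells took 20.9% ± 3.5 against 62.7% ± 6.0, a difference of −1.58 ± 0.55 that did not pass (adjusted p = 0.0564). Shares sum to 100%, so a rise in the share of 1 class lowers those of others, and the shares do not give cell numbers.

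In bone marrow, mature B-like cells took 3.87% ± 3.25 in B-ALL and 27.5% ± 4.3 in control (log2 difference −2.85 ± 0.59, adjusted p = 0.0147). Granulocyte-monocyte progenitor-like cells, which give rise to neutrophils and monocytes, were higher at 32.3% ± 4.2 against 13.9% ± 3.0 (1.22 ± 0.39, adjusted p = 0.0445). Non-classical monocyte-like cells took 5.48% ± 0.07 against 2.32% ± 0.09 (1.23 ± 0.35, adjusted p = 0.0314). The NK/T intermediate of cluster 27 was lower at 1.60% ± 0.88 against 5.10% ± 0.40 (−1.69 ± 0.46, adjusted p = 0.0296). T-like cells (−0.09 ± 0.43, adjusted p = 0.848) and NK-like cells (0.09 ± 0.32, adjusted p = 0.811) of marrow were not called. Of 26 such tests 8 passed. In blood the disease effect on shares exceeded that in marrow for non-classical monocyte-like cells by 2.39 ± 0.49 (adjusted p = 0.0142) and for classical monocyte-like cells by 2.64 ± 0.66 (adjusted p = 0.0234), 2 of 13 such tests. Among monocyte-like cells alone, the non-classical share was 43.5% ± 4.6 in B-ALL and 16.1% ± 1.6 in control marrow, and 92.7% ± 3.0 and 79.8% ± 5.1 in blood (exact permutation test, two-sided p = 0.33 in each, the smallest that 2 against 2 allows).

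Because genes that define clusters also differed with disease, the shares were counted again with cells clustered without the genes called between B-ALL and control. Non-classical monocyte-like cells were then higher by 3.65 in blood (adjusted p = 0.000109) and 1.65 in marrow (0.00583), progenitor-like cells by 1.64 (0.0180), NK-like cells of blood by 1.03 (0.0327) and classical monocyte-like cells of blood by 1.58 (0.0462), and T-like cells of blood were lower at −1.89 (0.00632). Mature B-like cells of marrow then missed the threshold (−1.76, adjusted p = 0.0598), as did the tissue difference of classical monocyte-like cells (0.59, 0.645). Other alternatives that keep all mice ended further calls. Progenitor-like cells missed the threshold in 4 of 8, namely in thinned cells (0.0609), at resolution 0.5 (0.0516), in rebuilt cells (0.0828) and over all cells (0.111). Classical monocyte-like cells of blood missed it in thinned cells (0.0609), and non-classical monocyte-like cells of marrow (0.111) and NK-like cells of blood (0.138) over all cells. Without called genes, the tissue difference of non-classical monocyte-like cells was 2.00 (0.0275), and the NK/T intermediate had no value in that clustering. The excess of non-classical cells among monocyte-like cells of marrow fell from 27.4 to 5.47 percentage points there. Without CON1 or without CON2, 1 of the 26 tests passed, that of non-classical monocyte-like cells in blood (3.36 to 3.91 over the 4 mice left out).

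**Figure D1:**
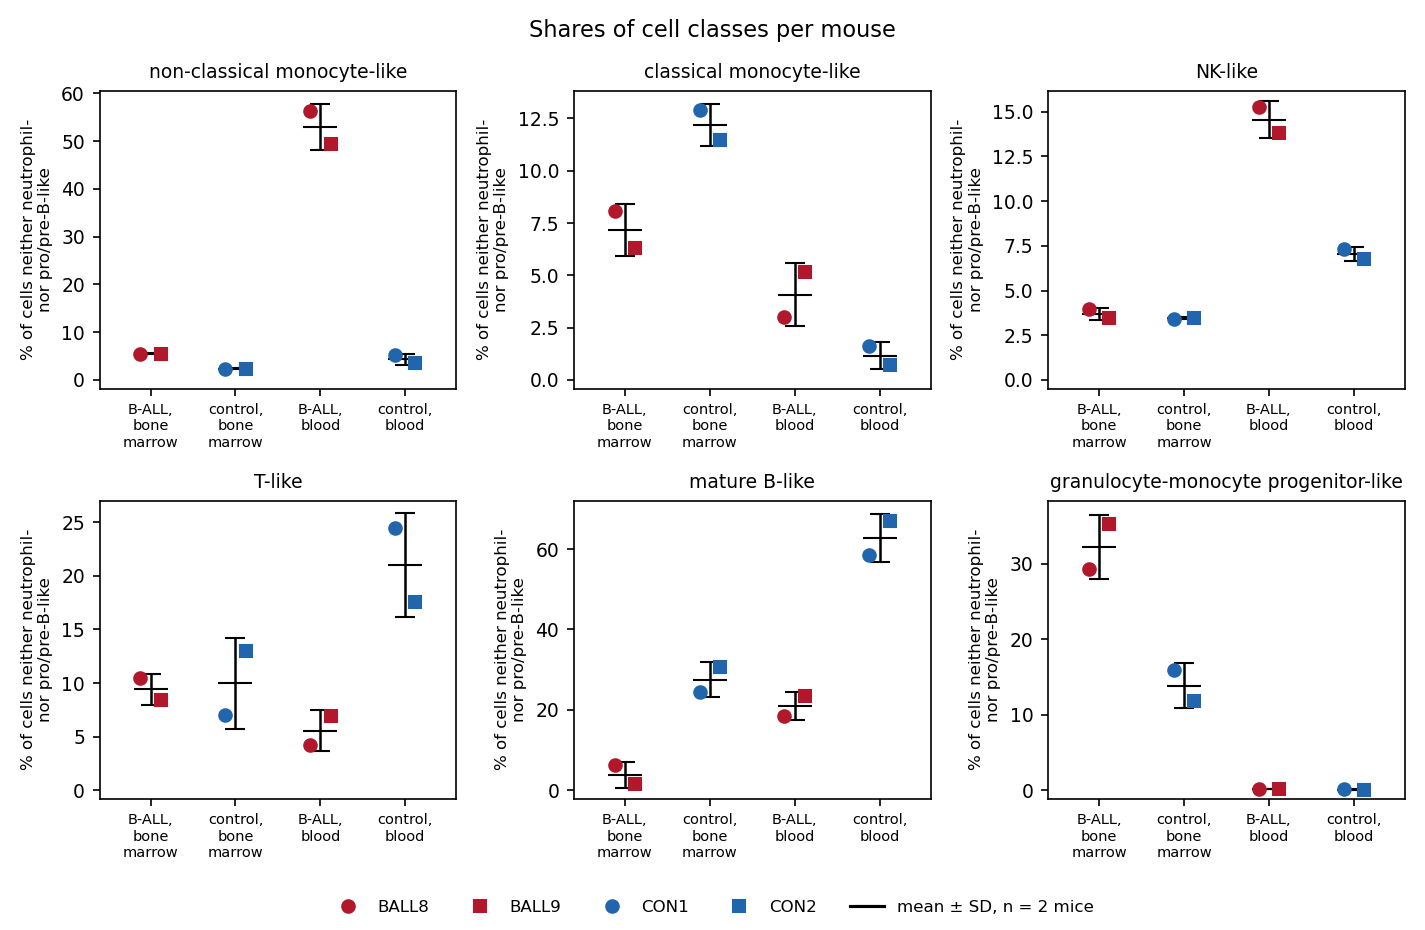
Shares of 6 cell classes per mouse, in percent of the cells that were neither neutrophil-like nor pro/pre-B-like (vertical axes), in B-ALL and control bone marrow and blood (horizontal axes). Points are mice (circles BALL8 and CON1, squares BALL9 and CON2), and horizontal and vertical lines are the mean ± SD of n = 2 mice; non-classical monocyte-like cells stood at 52.9% ± 4.9 of B-ALL blood and 4.33% ± 1.16 of control blood.

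Genes were then compared within each class, first in the non-classical monocyte-like cells of blood. Ikbke, a kinase of the interferon and NF-κB pathways (ENSMUSG00000042349, chromosome 1, 131254343 to 131279606 of GRCm38), stood at 167 ± 35.7 against 4.33 ± 0.532 CPM (SD, n = 2; log2 fold change 5.26 ± 0.49, adjusted p = 0.000803). Wnt6, a secreted Wnt ligand (ENSMUSG00000033227, chromosome 1, 74771892 to 74785322), stood at 94.7 ± 0.400 against 6.50 ± 0.797 CPM (3.87 ± 0.32, adjusted p = 0.000803). Tnip3, an inhibitor of NF-κB signalling (3.60 ± 0.34), Lifr, a cytokine receptor subunit (3.59 ± 0.49), Fpr1, a receptor for formylated peptides (4.55 ± 0.88), and Klhl6 (3.60 ± 0.83) were also higher. Upp1, uridine phosphorylase, and Arap2 had 1 count each over both control mice, and their count ratios were 55.0 (95% interval 9.86 to 2175) and 65.4 (95% interval 11.7 to 2584). Apoe, a lipid carrier (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was lower at 236 ± 272 against 4563 ± 882 CPM (−4.27 ± 0.97, adjusted p = 0.0384), with 428 CPM in BALL8 and 44.1 in BALL9. Lower too were Ccr2, the chemokine receptor of marrow exit (−4.18 ± 0.41, adjusted p = 0.000871), Mafb, a transcription factor of macrophages (−2.49 ± 0.31), P2ry6 (−2.73 ± 0.32), Hpgd, which inactivates prostaglandins (−2.25 ± 0.31), and Trf, transferrin (−2.23 ± 0.28).

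Among 15 measured immediate early genes, 5 fell over all genes and 10 over the list alone (camera adjusted p = 2.06e-06, or 0.345 with an estimated correlation). They included Fos (−2.92 ± 0.19, adjusted p = 7.87e-05), Dusp1 (−2.82 ± 0.30, adjusted p = 0.00135) and Zfp36 (−1.37 ± 0.15). Inflammatory genes of the NF-κB list had 13 measured members. Of these 4 rose over all genes and 6 over the list alone (camera adjusted p = 0.000189, or 0.362 with an estimated correlation), with Sod2 at 1.73 ± 0.31 and Cd14 at 2.52 ± 0.51. Of 11 heat shock genes 1 rose over all genes and 4 over the list alone (camera adjusted p = 0.00133, or 0.453 with an estimated correlation), led by Dnaja1 (1.25 ± 0.25). The 12 genes of the mitochondrial genome included 2 that fell over all genes and 3 over the list alone (camera adjusted p = 0.00188, or 0.589 with an estimated correlation). Interferon genes (0 of 18 called, 0 over the list alone, camera adjusted p = 0.771) gave no call. All 18 stood higher in BALL9 than in BALL8, as given under other observations, so the B-ALL mice did not act alike. Markers of neutrophils moved with these groups: of 8 genes 7 rose over all genes and 8 over the list alone (camera adjusted p = 3.40e-25, or 0.111 with an estimated correlation), with S100a8 at 5.14 ± 0.28. Of 6600 genes tested, 129 rose and 169 fell. Control blood held few cells of this class, 48 in CON1 and 50 in CON2, with 450834 and 534265 UMIs. B-ALL blood held 1843 in BALL8 and 1329 in BALL9, with 13453624 and 9474930 UMIs. B-ALL cells came from clusters 2 and 5, led by BALL8 and BALL9, and 89.8% of control cells from cluster 31. Cells of B-ALL held a median of 6988 and 6725 UMIs, against 8708.5 and 9003 in control. Without BALL8, BALL9, CON1 and CON2 the count of 298 became 946, 933, 2 and 4, and 0 of the 16 named genes kept their call without CON1 and 1 without CON2. With no filter it was 748 and with blood fitted alone 164, where Apoe and Klhl6 lost their calls, as Apoe did with free RNA subtracted.

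The same class was compared in bone marrow. Socs3, a feedback inhibitor of cytokine signalling, stood at 188 ± 50.8 against 12.6 ± 2.54 CPM (3.85 ± 0.49, adjusted p = 0.00402), and C3, the complement component, at 2.21 ± 0.16, adjusted p = 0.000560. Wnt6 was at least 11.5-fold higher, against 0 control counts. Ikbke (2 control counts), Upp1 (1) and Ccnd2, a cyclin (3), had count ratios of 38.8 (95% interval 10.6 to 323), 29.4 (95% interval 5.08 to 1179) and 26.3 (95% interval 8.85 to 129). Cd14, part of the endotoxin receptor, and Trem1, an activating receptor, each had 3 control counts and ratios of 13.8 (95% interval 4.57 to 68.3) and 13.2 (95% interval 4.35 to 65.2). Apoe (−4.82 ± 1.05, adjusted p = 0.0384), Trf (−3.37 ± 0.42, adjusted p = 0.00402), Ccr2 (−3.32 ± 0.45), Hpgd (−3.06 ± 0.37) and Clec2i (−2.19 ± 0.23) were lower. Of 13 inflammatory genes 7 rose over all genes and 9 over the list alone (camera adjusted p = 6.14e-07, or 0.348 with an estimated correlation), among them Sod2 (2.34 ± 0.39, adjusted p = 0.0147), Ccrl2 (3.28 ± 0.55) and Tnfaip3 (2.05 ± 0.35). The heat shock list had 11 members. Of these 2 rose over all genes and 6 over the list alone (camera adjusted p = 3.26e-05, or 0.394 with an estimated correlation), with Hspa8 at 1.70 ± 0.21, adjusted p = 0.00402. Neutrophil markers had 1 of 8 higher over all genes and 5 over the list alone (camera adjusted p = 0.00846, or 0.362 with an estimated correlation). Control marrow held 37 cells of this class in CON1 and 54 in CON2, with 182569 and 275376 UMIs. B-ALL marrow held 95 in BALL8 and 130 in BALL9, with 414385 and 532176 UMIs. Of 6600 genes 145 rose and 102 fell, and 91.2% of control cells lay in cluster 31. Without BALL8 and BALL9 the count of 247 became 565 and 610, and without CON1 and CON2 edgeR called 0 genes (1076 and 887 at an unadjusted p under 0.05). With no filter the count was 631, and Trem1 and Crebl2 lost their calls with cells rebuilt from the matrices, Trem1 also with doublets removed and Crebl2 with equal cell numbers.

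The disease effect of blood differed from that of marrow in 6 genes of this class. Hes1, a transcription factor of the Notch pathway, had a disease effect in blood that differed from that in marrow by −3.18 ± 0.28, adjusted p = 0.00184, and Actb, the cytoskeletal actin, one that differed by −1.0 ± 0.13, adjusted p = 0.0335. The 4 genes with a higher effect in blood were the neutrophil genes S100a8, S100a9, Ngp and Camp, which the rule for naming genes leaves out as markers of another cell type and which were named after their values were seen. Free RNA moved the same way. In near-empty droplets (at most 50 UMIs) the neutrophil list took 4.53% of UMIs in B-ALL and 1.53% in control blood, against 11.2% and 11.6% in marrow. With free RNA subtracted, or with genes of other cell types left out, the count was 1. With the mouse as a block the count was 203 (71 higher, 132 lower). It was 123 without BALL8 and 164 without BALL9, and 0 without CON1 or CON2 (635 and 511 at an unadjusted p under 0.05), and 70 with DESeq2 (17 higher, 53 lower). Hes1 and Actb lost their calls with equal cell numbers, and Actb also with free RNA genes left out, with free RNA subtracted and with doublets removed. Neither kept its call without CON1 or without CON2.

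**Figure D2:**
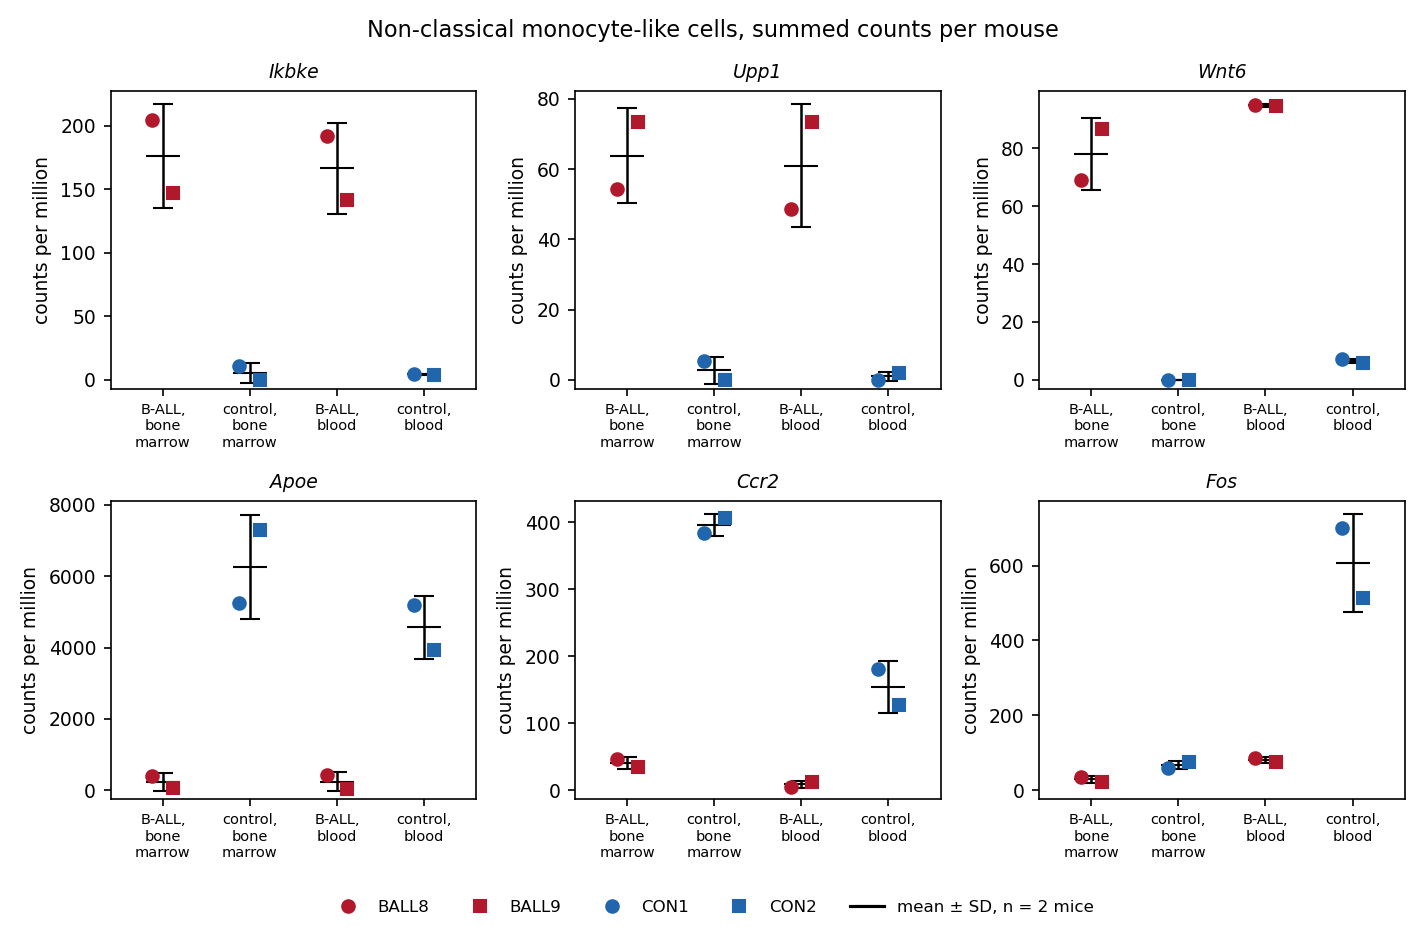
CPM (vertical axes) of 6 genes in summed non-classical monocyte-like cells of each mouse, in B-ALL and control bone marrow and blood (horizontal axes); points are mice and lines the mean ± SD of n = 2. Ikbke in blood stood at 167 ± 35.7 against 4.33 ± 0.532 CPM in B-ALL against control, and Apoe at 236 ± 272 against 4563 ± 882 CPM.

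Classical monocyte-like cells, the inflammatory monocytes that carry Ly6c2, were compared in bone marrow. Upp1 was higher at 48.4 ± 8.62 against 1.45 ± 0.658 CPM (5.05 ± 0.32, adjusted p = 0.00586; ENSMUSG00000020407, chromosome 11, 9118103 to 9136170). Fpr2, a receptor for formylated peptides (3.21 ± 0.52, adjusted p = 0.0366), Smpdl3b (3.08 ± 0.33), Socs3 (2.78 ± 0.49), Pla2g7, which degrades platelet-activating factor (2.64 ± 0.32), Ly6i (2.57 ± 0.41), Bcl2a1a (2.21 ± 0.28) and Ikbke (2.04 ± 0.25, adjusted p = 0.0217) were higher. Hpgd (−2.95 ± 0.45, adjusted p = 0.0313), Padi2 (−2.67 ± 0.33), Stxbp6 (−2.59 ± 0.34), Ckb (−2.42 ± 0.32), Clec2i (−2.38 ± 0.38), Trf (−2.19 ± 0.29), Mx1, an antiviral GTPase (−2.18 ± 0.41), and Cxcl9, a chemokine induced by interferon-γ (−2.16 ± 0.33, adjusted p = 0.0328), were lower. Of 22 proliferation genes 7 rose over all genes and 18 over the list alone (camera adjusted p = 1.25e-12, or 0.392 with an estimated correlation), with Birc5 at 1.32 ± 0.17 and Ccna2 at 1.22 ± 0.19. Inflammatory genes had 14 measured members. Of these 3 rose over all genes and 6 over the list alone (camera adjusted p = 2.29e-05, or 0.348 with an estimated correlation), such as Tnfaip3 (1.42 ± 0.21) and Icam1 (1.25 ± 0.24). Interferon response genes had 23. Of these 1 fell over all genes and 4 over the list alone (camera adjusted p = 1.30e-06, or 0.599 with an estimated correlation). The B-ALL mice stood apart in this list, with a median 1.47 higher in BALL9 than in BALL8 (23 of 23), against 0.09 between the control mice. The neutrophil list had 1 of 12 higher over all genes and 4 over the list alone (camera adjusted p = 0.0261, or 0.615 with an estimated correlation). Of 9227 genes 97 rose and 109 fell. Cluster 16 held 96.9% of the B-ALL cells and cluster 22 held 93.2% of the control cells. Without BALL8 and BALL9 the count of 206 became 1540 and 1846, and without CON1 and CON2 edgeR called 0 genes (926 and 1014 at an unadjusted p under 0.05). It was 712 with clusters at resolution 2, 646 with marrow fitted alone, 1279 with no filter and 62 with doublets removed, where Socs3, Ly6i, Hpgd, Clec2i, Mx1 and Cxcl9 lost their calls; Cxcl9 turned to 4.36 with equal cell numbers. Bcl2a1a, Mx1 and Cxcl9 lost their calls with cells rebuilt from the matrices and at resolution 2, Mx1 also with equal cell numbers and with tag ratios of at least 4.

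T-like cells of B-ALL blood carried more transcripts of checkpoint and effector genes and fewer of naive T cell genes than those of control blood. Maf, a transcription factor of effector and regulatory T cells (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794), stood at 391 ± 93.3 against 10.0 ± 0.856 CPM (5.25 ± 0.27, adjusted p = 1.69e-08), and Pdcd1, which encodes the checkpoint receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), at 98.6 ± 15.5 against 3.50 ± 2.57 CPM (4.78 ± 0.37, adjusted p = 5.76e-07). Gcg, the proglucagon gene, was at least 326-fold higher against 0 control counts. Arpp21 (−5.46 ± 0.85, adjusted p = 0.000450), Sox4 (−2.41 ± 0.61) and Rnaset2a (−2.15 ± 0.29) were lower. Of 10 checkpoint genes 7 rose over all genes and 8 over the list alone (camera adjusted p = 9.01e-09, or 0.362 with an estimated correlation), among them Lag3 (3.37 ± 0.43, adjusted p = 6.64e-05) and Ctla4 (2.29 ± 0.30). Cytotoxic and effector genes had 15 measured members. Of these 10 rose over all genes and 12 over the list alone (camera adjusted p = 2.66e-07, or 0.392 with an estimated correlation), with Ifng, interferon-γ, at 4.76 ± 0.32, adjusted p = 1.15e-07 and Gzmb, granzyme B, at 3.47 ± 0.39. Of 12 naive and memory genes 6 fell over all genes and 9 over the list alone (camera adjusted p = 8.87e-06, or 0.501 with an estimated correlation), such as Ccr7, the homing receptor of lymph nodes (−1.76 ± 0.23), and Tcf7 (−1.01 ± 0.18). Proliferation genes numbered 22. Of these 18 rose over all genes and 18 over the list alone (camera adjusted p = 1.29e-08, or 0.453 with an estimated correlation), and of 22 ribosomal protein genes 19 fell over all genes and 22 over the list alone (camera adjusted p = 4.28e-13, or 0.453 with an estimated correlation).

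Neutrophil markers moved with these groups in T-like cells of blood, where 9 of 11 rose over all genes and 11 over the list alone (camera adjusted p = 1.61e-13, or 0.362 with an estimated correlation). In the same cells 10 of 12 genes of the mitochondrial genome fell over all genes and 11 over the list alone (camera adjusted p = 5.15e-13, or 0.362 with an estimated correlation). The mitochondrial share was lower over all cells of the B-ALL libraries, so such a fall is not particular to a class. Median UMIs per cell were 5525 in BALL8 and 6278 in BALL9, against 8353 in CON1 and 8580 in CON2. Of 8959 genes 912 rose and 682 fell, with 5 of 13 T cell markers among the lower and 1 among the higher. These markers, named outside the rule, were Bcl11b, Cd4, Cd8a, Cd8b1, Lef1 and Trbc2. Cluster 12 held 49.2% of the B-ALL cells and 7.95% of the control cells, and cluster 13 held 36.2% and 57.9%. Cluster 29 held 13.6% and 24.5%, and cluster 36 held 0.93% and 9.62%. In both tissues a change within T-like cells cannot be told apart from the mix of clusters. The count of 1594 became 952 without BALL9, 909 without CON1 and 734 without CON2, and 618 with DESeq2, where Arpp21 and Sox4 lost their calls. Sox4 also lost its call without BALL9 and without the Arpp21-rich cluster 36.

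In T-like cells of bone marrow, Lag3, a checkpoint receptor (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705), stood at 49.5 ± 22.5 against 4.86 ± 0.316 CPM (3.33 ± 0.57, adjusted p = 0.00380), and Ccl3, a chemokine, was higher by 4.48 ± 0.93, adjusted p = 0.0109. Gcg was at least 8.7-fold higher against 0 control counts. Dapl1 (−3.50 ± 0.39, adjusted p = 0.000446), Rapgef4 (−3.15 ± 0.43) and Tdrp (−2.81 ± 0.49) were lower. Checkpoint genes had 10 measured members. Of these 5 rose over all genes and 10 over the list alone (camera adjusted p = 8.09e-08, or 0.362 with an estimated correlation), with Pdcd1 at 3.23 ± 0.37. Cytotoxic and effector genes numbered 15. Of these 6 rose over all genes and 10 over the list alone (camera adjusted p = 2.38e-05, or 0.453 with an estimated correlation), with Gzmb at 2.61 ± 0.48. Naive and memory genes fell in 9 of 12 cases over all genes and 11 over the list alone (camera adjusted p = 1.29e-10, or 0.405 with an estimated correlation), Ccr7 (−2.25 ± 0.32) and S1pr1, a receptor of tissue exit (−1.90 ± 0.26), among them. Their median was 1.16 lower in BALL9 than in BALL8, against a difference of 0.01 between the control mice. Of 23 interferon genes 10 fell over all genes and 13 over the list alone (camera adjusted p = 2.70e-08, or 0.489 with an estimated correlation), with Ifit3 at −2.69 ± 0.39. The B-ALL pair and the control pair of mice each stood apart in this list, with values under other observations. In blood 2 of 23 rose (2 over the list alone; camera adjusted p = 0.429, or 0.930 with an estimated correlation). The test of the difference between tissues gave 1 of 23 with a higher effect in blood over all genes and 15 over the list alone (camera adjusted p = 1.01e-09, or 0.453 with an estimated correlation), Oasl2 among them (3.12 ± 0.65, adjusted p = 0.0313). Neutrophil markers had 3 of 11 higher in marrow (8 over the list alone; camera adjusted p = 0.000188, or 0.515 with an estimated correlation).

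Of the 8959 genes tested in T-like cells of marrow, 230 rose and 238 fell. In these cells, too, 8 of 12 genes of the mitochondrial genome fell over all genes and 11 over the list alone (camera adjusted p = 1.03e-10, or 0.362 with an estimated correlation). Median UMIs per cell were 2784 in BALL8 and 2823 in BALL9, against 5307 in CON1 and 5245 in CON2. Cluster 12 held 82.7% of B-ALL and 38.7% of control cells, and cluster 13 held 51.5% of control cells. The count of 468 became 749 without BALL8, 98 without BALL9, 241 without CON1 and 109 without CON2, and the call of Lag3 and 3 others of the 6 named genes was lost in some of these, while Dapl1 and Rapgef4 kept theirs in each. It was 229 with DESeq2 (77 up, 152 down), 193 with equal cell numbers and 815 with no filter, and Ccl3 was −0.05 with cells rebuilt from the matrices. Gcg lost its call with DESeq2 and with equal cell numbers, and Ccl3 with the latter. The test of the difference between tissues called 66 genes (42 higher in blood, 24 lower), which became 39 without CON1 and 21 without CON2, and 33 with equal cell numbers.

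**Figure D3:**
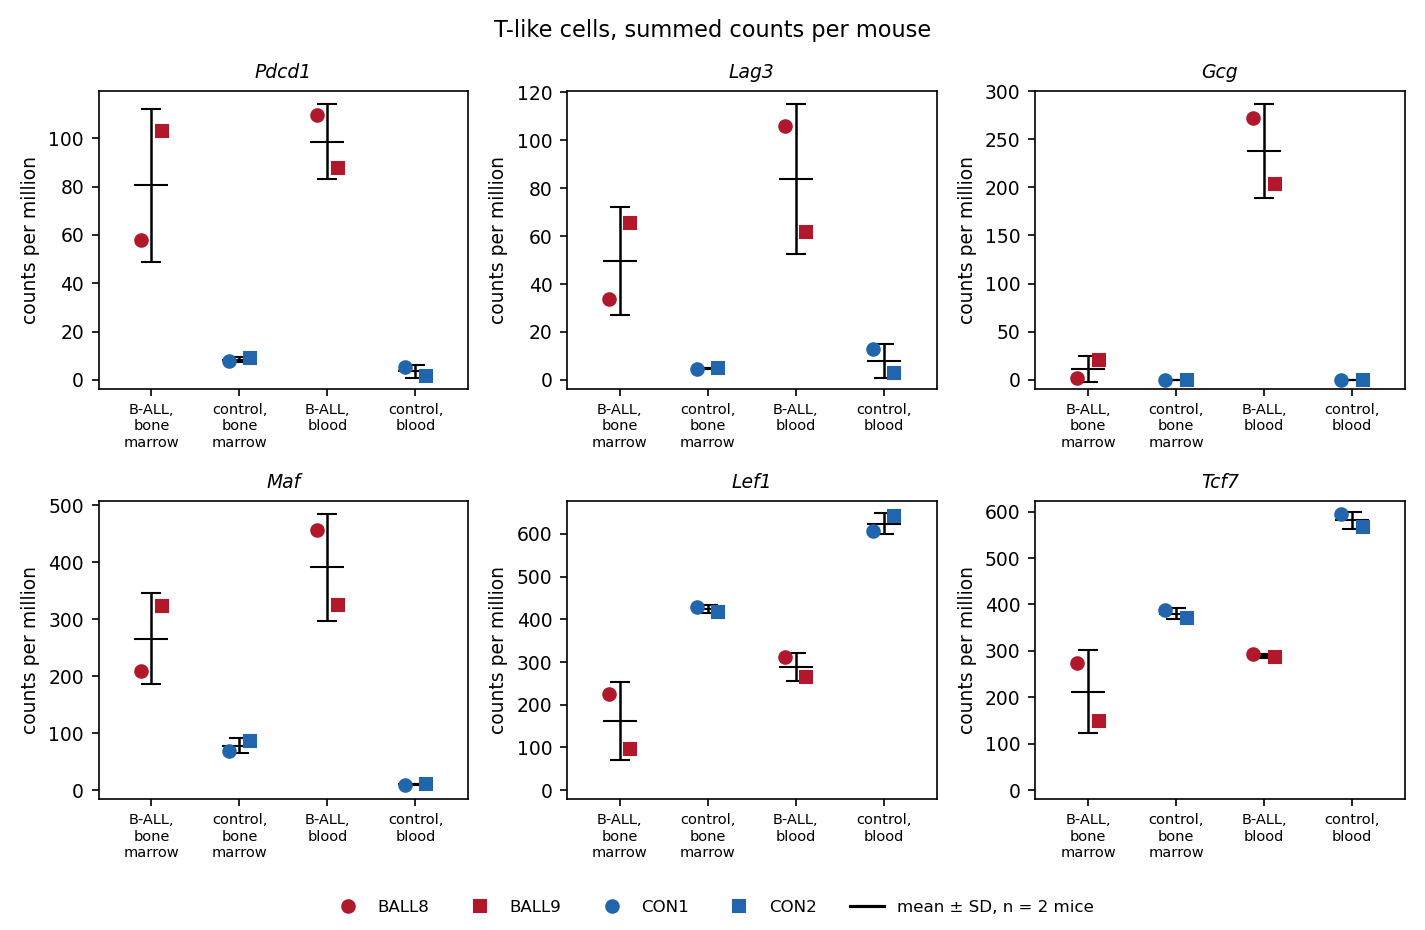
CPM (vertical axes) of 6 genes in summed T-like cells of each mouse, in B-ALL and control bone marrow and blood (horizontal axes); points are mice and lines the mean ± SD of n = 2. Pdcd1 in blood stood at 98.6 ± 15.5 against 3.50 ± 2.57 CPM in B-ALL against control, and Maf at 391 ± 93.3 against 10.0 ± 0.856 CPM.

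NK-like cells of blood showed higher proliferation genes in B-ALL. Of 22 measured, 10 rose over all genes and 18 over the list alone (camera adjusted p = 7.59e-14, or 0.450 with an estimated correlation), among them Ube2c (4.25 ± 0.62, adjusted p = 0.00270) and Ccnb1, cyclin B1 (3.77 ± 0.79). The control mice stood apart in this list, with a median 2.24 lower in CON2 than in CON1 (1 of 22 higher), and that of BALL9 was 0.94 above that of BALL8 (22 of 22). Ribosomal protein genes numbered 22. Of these 17 rose over all genes and 20 over the list alone (camera adjusted p = 2.34e-20, or 0.384 with an estimated correlation). Plac8 (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245) was higher by 4.82 ± 0.34, adjusted p = 2.31e-05 and Ifitm3, an antiviral membrane protein, by 4.35 ± 0.77, adjusted p = 0.00749. Hp, haptoglobin, had 1 control count and a ratio of 55.0 (95% interval 9.81 to 2179). Its source was not tested, and doublets with neutrophils remain a candidate source of neutrophil transcripts in this class, as weighed below. Xcl1, a chemokine of NK cells (−2.31 ± 0.43, adjusted p = 0.01), and Dusp2 (−1.97 ± 0.24) were lower, as were 5 of 11 NK markers. Neutrophil markers moved with these groups, where 6 of 9 rose over all genes and 8 over the list alone (camera adjusted p = 7.22e-15, or 0.362 with an estimated correlation). In these cells, too, 4 of 12 genes of the mitochondrial genome fell over all genes and 7 over the list alone (camera adjusted p = 7.89e-07, or 0.348 with an estimated correlation). Median UMIs per cell were 6512 and 7310 in B-ALL against 6868 and 6311 in control. Of 7274 genes 224 rose and 159 fell. Cluster 34 held 9.66% of the B-ALL and 0.61% of the control cells of blood, and 2.67% and 9.63% of those of marrow. Cluster 7 held the rest. The tests do not separate a change within cells from this mix of clusters. In marrow 5 genes were called: Gzma, granzyme A (1.13 ± 0.10, adjusted p = 0.000281), Klrg1, a receptor of mature NK cells (2.12 ± 0.27, adjusted p = 0.0115), and Il7r (2.43 ± 0.39, adjusted p = 0.0454) were higher, Ccr2 was lower (−1.28 ± 0.19, adjusted p = 0.0290), and the last was a marker of another cell type. NK maturation genes of marrow numbered 15. Of these 3 rose over all genes and 6 over the list alone (camera adjusted p = 4.12e-06, or 0.362 with an estimated correlation).

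The count of 383 in NK-like cells of blood became 682 without BALL8, 63 without CON1 and 12 without CON2, 184 with DESeq2, 104 with free RNA subtracted (44 up, 60 down), 236 with equal cell numbers and 795 with no filter, and of the 6 named genes Plac8 alone kept its call without each mouse in turn. Xcl1 also lost its call with DESeq2. The 5 calls of marrow became 19 without BALL8 and 20 without BALL9, 0 by edgeR without CON1 or CON2 (536 and 664 at an unadjusted p under 0.05), 29 with DESeq2, 12 with marrow fitted alone or free RNA subtracted and 131 with no filter. Il7r lost its call with cells rebuilt from the matrices, at resolution 2 and with marrow fitted alone, and Klrg1 and Ccr2 with equal cell numbers. Median UMIs per cell of marrow were 2864 and 3610 in B-ALL against 6211 and 6655 in control. Between tissues, the effect on 56 genes differed (38 higher in blood, 18 lower), and on 356 with the mouse as a block (270 higher, 86 lower). Proliferation genes had 7 of 22 with a higher effect in blood over all genes and 15 over the list alone (camera adjusted p = 4.66e-14, or 0.447 with an estimated correlation), and NK maturation genes 4 of 15 with a lower one and 1 with a higher one (7 and 1 over the list alone; camera adjusted p = 4.83e-05, or 0.374 with an estimated correlation). That count was 140 without BALL8, 137 without BALL9, 2 without CON1 and 1 without CON2.

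Mature B-like cells of B-ALL blood had more transcripts of proliferation and MYC target genes and fewer of B cell maturation and class II antigen presentation genes. Mki67, a proliferation marker (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), stood at 53.6 ± 10.2 against 3.29 ± 3.34 CPM (3.75 ± 0.30, adjusted p = 7.53e-07), and Hsph1, a heat shock protein, was higher by 2.85 ± 0.45, adjusted p = 0.000356. Chil3 was higher by 3.74 ± 0.41, adjusted p = 2.06e-05 and lost its call with free RNA subtracted. That loss cannot tell its source, since the subtraction took 2.76 times the neutrophil RNA seen in lymphoid cells of B-ALL blood. Fcer2a, which encodes the low-affinity IgE receptor CD23 (−1.90 ± 0.22, adjusted p = 3.19e-05; ENSMUSG00000005540, chromosome 8, 3681737 to 3694175), Dusp1 (−1.92 ± 0.18, adjusted p = 4.45e-06) and Pxdc1 (−1.81 ± 0.17) were lower. Of 22 proliferation genes 17 rose over all genes and 18 over the list alone (camera adjusted p = 7.67e-12, or 0.362 with an estimated correlation), with Top2a at 2.39 ± 0.27. The MYC target list had 16 members. Of these 13 rose over all genes and 15 over the list alone (camera adjusted p = 3.50e-11, or 0.412 with an estimated correlation), such as Nolc1 (1.24 ± 0.12) and Ncl (0.92 ± 0.13). Class II antigen presentation genes numbered 11. Of these 11 fell over all genes and 11 over the list alone (camera adjusted p = 1.05e-10, or 0.374 with an estimated correlation), with Ciita, their transactivator, at −0.84 ± 0.13 and H2-Eb1 at −0.73 ± 0.13. Of 14 B cell maturation genes 10 fell over all genes and 10 over the list alone (camera adjusted p = 7.64e-10, or 0.362 with an estimated correlation), among them Fcmr (−1.35 ± 0.12) and Cr2 (−1.17 ± 0.15). Neutrophil markers moved with these groups, with 8 of 12 higher over all genes and 9 over the list alone (camera adjusted p = 6.80e-09, or 0.362 with an estimated correlation). In these cells, too, 7 of 12 genes of the mitochondrial genome fell over all genes and 8 over the list alone (camera adjusted p = 2.32e-07, or 0.348 with an estimated correlation). Their median UMIs per cell were 4171 and 4281 in B-ALL against 5813 and 5900 in control. Of 10527 genes 1110 rose and 952 fell. DESeq2 called 1269 of them, and without BALL8, BALL9, CON1 and CON2 the count of 2062 was 2607, 2157, 755 and 961, with all 6 named genes called each time.

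In bone marrow, 20 genes rose and 38 fell in mature B-like cells. S100a6, a calcium-binding protein (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181; 3.78 ± 0.47, adjusted p = 0.00197), Ptpn22 (2.96 ± 0.58) and Ahnak (2.31 ± 0.30) were higher, and Myl4 (−2.64 ± 0.44, adjusted p = 0.00945), Il4i1 (−2.21 ± 0.45) and Coq7 (−1.98 ± 0.38) lower. Of 16 MYC target genes 1 rose over all genes and 4 over the list alone (camera adjusted p = 1.62e-05, or 0.527 with an estimated correlation), the first being Myc itself (2.26 ± 0.32, adjusted p = 0.00354). The list was 0.48 higher in BALL9 than in BALL8, against −0.02 in the control pair (CON2 minus CON1). The 58 calls became 208 without BALL9 and 110 without CON2, 124 with DESeq2 (69 up, 55 down), 104 with marrow fitted alone, 222 with no filter and 7 with equal cell numbers, and of the 6 named genes S100a6 and Ahnak kept their calls without each mouse in turn. Ptpn22, Myl4, Il4i1 and Coq7 also lost theirs with equal cell numbers, and Ptpn22 with free RNA subtracted. Median UMIs per cell were 1962 and 1992 in B-ALL against 3756 and 3609 in control. Cluster 0 held 67.6% of the B-ALL and 49.4% of the control cells of marrow, and cluster 10 held 26.2% and 49.9%. The disease effect differed between tissues in 30 genes (16 higher in blood, 14 lower), and in 199 with the mouse as a block (110 higher, 89 lower). That count was 14 without BALL8, 117 without BALL9 and 90 without CON2, and 72 with DESeq2 (23 higher, 49 lower).

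Neutrophil-like cells of B-ALL blood carried more transcripts of the neutrophil list than those of control blood. Control blood held few of them, 108 in CON1 and 31 in CON2, with 479128 and 166841 UMIs. B-ALL blood held 334 in BALL8 and 489 in BALL9. All 12 genes of the neutrophil list rose over all genes and over the list alone (camera adjusted p = 4.33e-06, or 0.445 with an estimated correlation), with Cd177 at 5.21 ± 0.23, adjusted p = 1.34e-08. Of 13 markers of this class 11 rose and 1 fell. Itgb2l, Orm1 and Stfa1 were at least 68.9-, 61.3- and 39.8-fold higher against 0 control counts. Hist1h2bc (−3.02 ± 0.15, adjusted p = 5.38e-08), Dusp1 (−2.33 ± 0.24, adjusted p = 2.21e-05) and Fgl2 (−2.24 ± 0.19) were lower. Of 16 immediate early genes 7 fell over all genes and 9 over the list alone (camera adjusted p = 0.000368, or 0.534 with an estimated correlation), such as Atf3 (−4.04 ± 0.46), and of 22 proliferation genes 11 rose over all genes and 13 over the list alone (camera adjusted p = 1.48e-07, or 0.348 with an estimated correlation). Platelet markers moved with these groups, where 5 of 6 fell over all genes and 5 over the list alone (camera adjusted p = 0.000292, or 0.419 with an estimated correlation). The B-ALL mice stood apart in these cells: BALL9 lay above BALL8 by a median log2 difference of 1.19 for the platelet list (5 of 6), 5.05 for the erythroid list (7 of 7) and 1.32 for interferon genes (22 of 22). Of 10559 genes 1166 rose and 471 fell. Scaling moved this split: the median log2 fold change of all genes was 0.30 with TMM and 0.13 with RLE size factors, which gave 858 up and 670 down, and DESeq2 gave 799 and 801. Cluster 9 held all control cells and 61.1% of the B-ALL cells. The count of 1637 became 557 without CON1 and 505 with equal cell numbers, while 5 of the 6 named genes, Stfa1 excepted, kept their calls without each mouse in turn. Stfa1 also lost its call with equal cell numbers.

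In bone marrow, Lipg, endothelial lipase (ENSMUSG00000053846, chromosome 18, 74939322 to 74961263), was higher in neutrophil-like cells of B-ALL by 3.74 ± 0.22, adjusted p = 6.29e-06, as were Upp1 (2.69 ± 0.32) and Stfa1 (2.28 ± 0.33). St8sia4 (−1.89 ± 0.19, adjusted p = 0.000396), Ccl6 (−1.50 ± 0.25) and Il1b, interleukin-1β (−1.32 ± 0.24, adjusted p = 0.0164), were lower, Il1b without a call when free RNA was subtracted. Of 22 ribosomal protein genes 2 rose over all genes and 21 over the list alone (camera adjusted p = 1.63e-27, or 0.362 with an estimated correlation). Their median was 0.32 higher in BALL9 than in BALL8 (22 of 22), and median UMIs per cell were 6327.5 and 8106.5 in B-ALL against 13988 and 12371.5 in control. The class I antigen presentation list had 12. Of these 3 rose over all genes and 4 over the list alone (camera adjusted p = 0.00139, or 0.555 with an estimated correlation), such as H2-Q6 (1.27 ± 0.24). Of 10559 genes 112 rose and 62 fell. Without BALL8, BALL9, CON1 and CON2 the count of 174 was 1263, 2083, 3 and 13, where Lipg and St8sia4 kept their calls. It was 436 with equal cell numbers, 690 with no filter, 115 with marrow fitted alone, where Stfa1 lost its call, and 55 with free RNA subtracted. The effect differed between tissues in 1133 genes (861 higher in blood, 272 lower), at a median of 0.29 with TMM and 0.14 with RLE size factors (686 higher, 408 lower). DESeq2 gave 658 and 499. That count was 433 without CON2, 204 without CON1 and 352 with equal cell numbers.

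Pro/pre-B-like cells of B-ALL marrow, among them the sorted GFP+CD19+ blasts, were compared with the pro/pre-B-like cells of control marrow, the B cell precursors of healthy mice. Sln, sarcolipin (ENSMUSG00000042045, chromosome 9, 53850164 to 53854560), was at least 832-fold higher and Ddx3y, a Y-linked helicase gene (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), at least 313-fold, against 0 control counts. Tubb3, a tubulin of neurons (2 control counts), Sema6d (1) and Ryr2, a calcium channel (3), had count ratios of 751 (95% interval 207 to 6204), 470.4 (95% interval 84.0 to 18618) and 409.5 (95% interval 139.8 to 1988). Foxc1, a transcription factor (7.07 ± 0.54, adjusted p = 0.00229), Rnase12 (6.85 ± 0.74) and Tmem119 (6.57 ± 1.13) were higher. Dntt, the terminal transferase that adds bases at receptor gene joints (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), was lower at 0.683 ± 0.276 against 160.1 ± 18.8 CPM (−7.91 ± 0.32, adjusted p = 0.000591). Nrgn (−8.27 ± 0.42, adjusted p = 0.000867), Xist, the RNA of the inactive X chromosome (−5.29 ± 0.28, adjusted p = 0.000867), Spns3 (−4.66 ± 0.41), Adam19 (−4.43 ± 0.31), Hdac5 (−4.42 ± 0.15), H2-Aa (−3.66 ± 0.60) and Col5a3 (−3.59 ± 0.67) were lower. Ddx3y and Xist depend on the sex of the cells, so their calls need not be changes with leukaemia, a point weighed below.

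The list of JAK-STAT targets held 12 measured genes. Of these 6 rose over all genes and 7 over the list alone (camera adjusted p = 0.00411, or 0.362 with an estimated correlation). Feedback inhibitors of cytokine signalling were among them, Socs2 (2.70 ± 0.14, adjusted p = 0.000867) and Cish (3.87 ± 0.24, adjusted p = 0.00152), beside the kinase gene Pim1 (1.08 ± 0.13). Of 18 glycolysis and hypoxia genes 9 rose over all genes and 14 over the list alone (camera adjusted p = 7.20e-06, or 0.384 with an estimated correlation), with Vegfa at 1.86 ± 0.24 and Pfkp at 1.87 ± 0.29. Depth moved with these groups, at median UMIs per cell of 11200 and 12668.5 in B-ALL against 4416 and 4311 in control. B cell maturation genes numbered 14. Of these 5 fell over all genes and 7 over the list alone (camera adjusted p = 4.16e-05, or 0.348 with an estimated correlation), with Ighm, the IgM heavy chain, at −1.74 ± 0.08. Genes of the pre-B cell receptor and B progenitors went both ways, 5 of 17 up and 6 down over all genes and 5 and 8 over the list alone (camera adjusted p = 0.349), with Vpreb1 at 1.73 ± 0.15. Of 11565 genes 900 rose and 804 fell, and 9 of 12 markers of this class changed. Clusters 17, 23 and 26 held 39.1%, 30.5% and 24.2% of the B-ALL cells, and clusters 8, 15 and 30 held 55.0%, 33.1% and 11.8% of the control cells. Without BALL8, BALL9, CON1 and CON2 the count of 1704 was 5645, 6271, 86 and 102, and 10 of the 16 named genes kept their calls each time, Dntt, Xist, Sln and Foxc1 among them. With marrow fitted alone it was 2558.

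Pro/pre-B-like cells of B-ALL were then compared between blood and marrow. In blood, Ms4a1, which encodes the B cell antigen CD20 (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), stood at 249 ± 60.3 against 9.79 ± 6.25 CPM (4.71 ± 0.48, adjusted p = 0.00434), and Klf2, a transcription factor of lymphocyte quiescence and migration (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), at 755 ± 182 against 35.2 ± 5.19 CPM (4.42 ± 0.22, adjusted p = 0.00190). S100a6 stood at 12366 ± 1769 against 733 ± 35.1 CPM (4.08 ± 0.17) and Cd74, the class II invariant chain, at 2127 ± 744 against 113 ± 59.9 CPM (4.24 ± 0.46, adjusted p = 0.00523). Ly6a (4.71 ± 0.83), Lmna, a nuclear lamin (4.60 ± 0.34), Rassf4 (3.92 ± 0.32) and Myadm (3.84 ± 0.18) were also higher. Cenpf, a kinetochore protein (ENSMUSG00000026605, chromosome 1, 189640606 to 189688086), was lower at 58.0 ± 10.1 against 500.4 ± 125 CPM (−3.11 ± 0.27, adjusted p = 0.00306), with Plk1, a mitotic kinase (−3.07 ± 0.26), Kif20a (−3.23 ± 0.24), Sapcd2 (−3.08 ± 0.27), Hist1h3c (−3.06 ± 0.47), Pimreg (−3.05 ± 0.31) and Adgrg1 (−3.52 ± 0.15). Chil3, a myeloid gene, was lower by −5.96 ± 0.50, adjusted p = 0.00305 and lost its call with free RNA subtracted.

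Of 22 proliferation genes 19 fell over all genes and 21 over the list alone (camera adjusted p = 5.70e-13, or 0.450 with an estimated correlation), with Mki67 at −3.02 ± 0.18 and Top2a at −2.40 ± 0.21. Immediate early genes had 17 measured members. Of these 13 rose over all genes and 14 over the list alone (camera adjusted p = 2.03e-10, or 0.362 with an estimated correlation), such as Nr4a1 (3.75 ± 0.25) and Klf6 (2.68 ± 0.13). The 11 class II genes included 4 that rose over all genes and 9 over the list alone (camera adjusted p = 0.000482, or 0.441 with an estimated correlation), and of 12 class I genes 5 rose over all genes and 5 over the list alone (camera adjusted p = 0.000928, or 0.637 with an estimated correlation), B2m (1.26 ± 0.22) among them. B cell maturation genes numbered 14. Of these 6 rose over all genes and 11 over the list alone (camera adjusted p = 2.58e-05, or 0.348 with an estimated correlation), and of 17 pre-B cell receptor and progenitor genes 9 fell over all genes and 9 over the list alone (camera adjusted p = 0.00101, or 0.453 with an estimated correlation), with Igll1 at −1.51 ± 0.11. Markers of other cells moved too: of 14 non-classical monocyte genes 9 rose over all genes and 12 over the list alone (camera adjusted p = 3.84e-07, or 0.385 with an estimated correlation), with Ace at 4.65 ± 0.46, and of 12 neutrophil genes 8 fell over all genes and 10 over the list alone (camera adjusted p = 2.82e-07, or 0.497 with an estimated correlation). Of 11565 genes 1014 rose and 1068 fell. Blood cells lay in clusters 18 (59.6%) and 28 (32.4%). Without BALL8, BALL9, CON1 and CON2 the count of 2082 was 5246, 5195, 625 and 624, and all 16 named genes kept their calls each time.

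**Figure D4:**
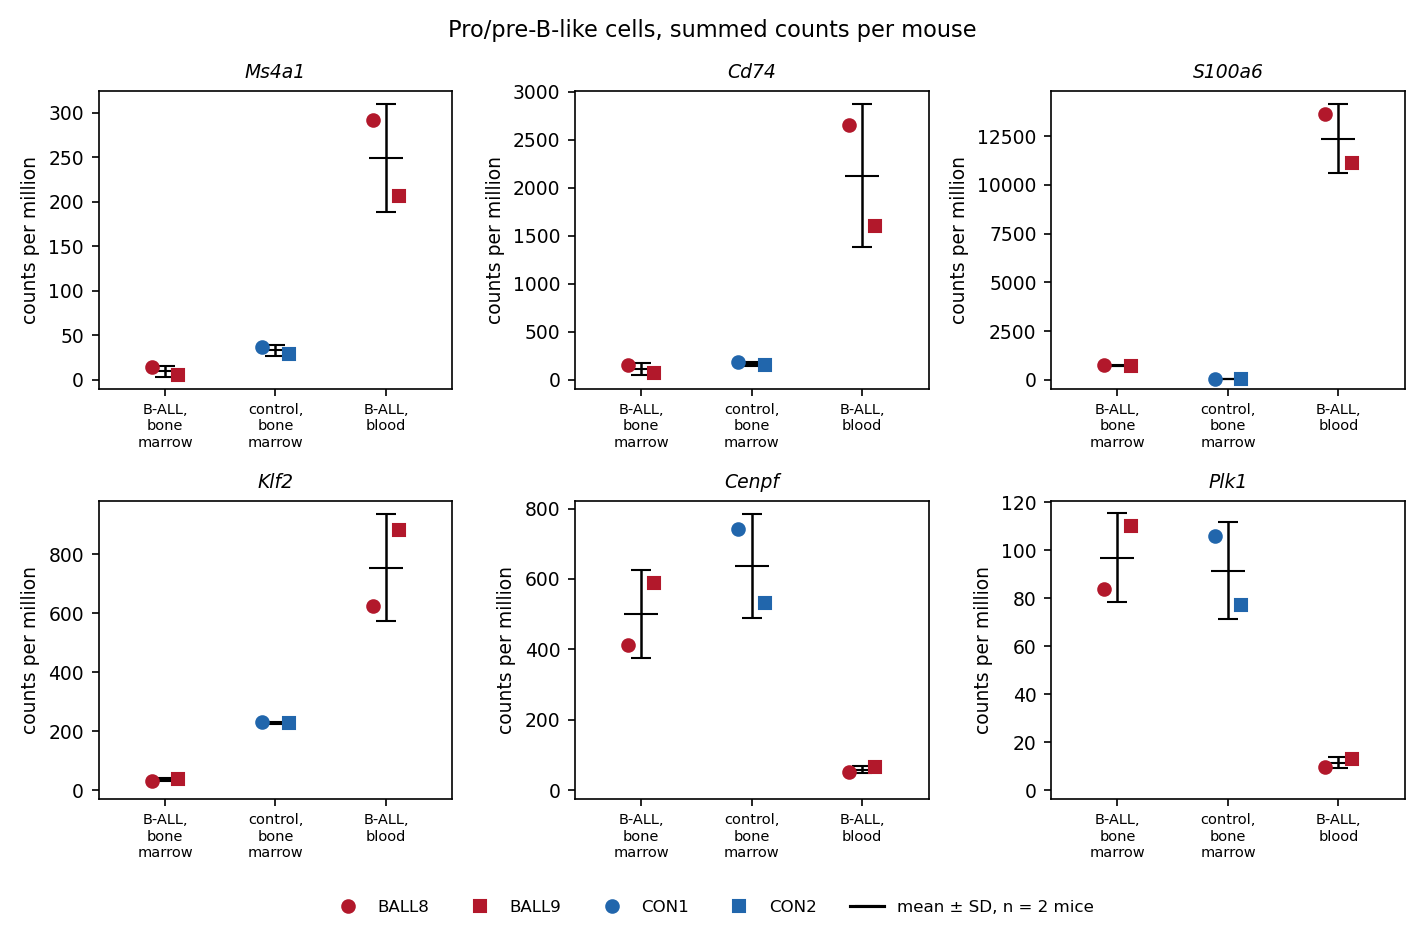
CPM (vertical axes) of 6 genes in summed pro/pre-B-like cells of each mouse, in B-ALL bone marrow, control bone marrow and B-ALL blood (horizontal axes); points are mice and lines the mean ± SD of n = 2. Klf2 stood at 755 ± 182 against 35.2 ± 5.19 CPM in B-ALL blood against B-ALL marrow, and Cenpf at 58.0 ± 10.1 against 500.4 ± 125 CPM.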

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

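The tests of the explanations below were all chosen after the results were seen, while the tests of a difference between tissues were planned. Each result here is a disease effect, B-ALL against control, that differed between blood and bone marrow in edgeR's quasi-likelihood test of the difference, adjusted within each cell class. Such genes numbered 6 in non-classical monocyte-like cells, 1133 in neutrophil-like cells, 66 in T-like cells, 56 in NK-like cells and 30 in mature B-like cells. These counts come from a fit that does not pair the tissues of a mouse. With the mouse as a block, those of non-classical monocyte-like, NK-like and mature B-like cells rose by more than 1.5 times, as given below. The effect on cell shares was higher in blood by 2.64 on the log2 scale for classical and by 2.39 for non-classical monocyte-like cells. The values of the next paragraph are effects in blood minus effects in marrow on the log2 scale.

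In non-classical monocyte-like cells the values were −3.18 for Hes1 and −1.0 for Actb. In neutrophil-like cells they were 14.38 for Itgb2l, 13.35 for Orm1 and 12.52 for Abca13, fitted values against control blood with 0 counts that give no bound, and −2.64 for Hist1h2bc, −2.18 for Socs3 and −2.02 for Nrros. T-like cells gave 3.52 for Maf, 3.23 for Ifitm3, 3.06 for Lgals3, −2.45 for Rnaset2a, −2.32 for Ramp1 and −1.91 for Cxcr4. NK-like cells gave 7.07 for Cenpf, 6.29 for Ube2c and 6.27 for Aspm, which rest on 8, 9 and 3 counts in control blood, and −2.56 for Dusp2, −2.45 for Tsc22d3 and −2.29 for Rgs1. Mature B-like cells gave 4.02 for Mki67, 3.03 for Pclaf, 2.63 for Ccnd2, −2.52 for Cxcr4, −2.27 for Tsc22d3 and −1.73 for Myc. Of these genes Maf, Ube2c, Mki67, Ccnd2, Tsc22d3 of mature B-like cells, and in neutrophil-like cells Itgb2l, Orm1, Abca13, Hist1h2bc and Nrros kept their calls without each mouse in turn. Under 1 or more alternatives that keep all mice, calls were lost by Hes1, Actb, Socs3, all named genes of T-like cells but Maf, Cenpf, Ube2c (rebuilt cells), Tsc22d3 of NK-like cells, Pclaf, Ccnd2 (equal cell numbers, free RNA subtraction), Cxcr4 of mature B-like cells and Myc.

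Neutrophil transcripts in lymphoid cells of B-ALL blood were the first pattern weighed. T-like, NK-like and mature B-like cells held 645, 1480 and 709 CPM of the neutrophil list, against 43.2, 45.4 and 151 in control blood, and a median of 4 UMIs per cell in each class (NK-like cells of the B-ALL mice stood apart, 1.99 higher on the log2 scale in BALL9 than in BALL8 over 9 of 9 genes, against −0.58 and −0.02 in T-like and mature B-like cells). In T-like and mature B-like cells the 5% of cells with most of them held 13.9% of these UMIs (median of both classes), under the 25% set as the bound against doublets, so doublets do not account for them there. In NK-like cells the top 5% held 66.4%, and doublets with neutrophils remain a candidate source for that part. Free RNA of neutrophils remains open in all 3 classes. The neutrophil share was 0.28 times (range 0.16 to 1.63 over mice and classes) what near-empty droplets would bring at the free RNA share read from a lymphoid list. That test uses B-ALL blood alone, so it cannot decide the difference from control. The list took 4.53% of near-empty UMIs in B-ALL and 1.53% in control blood. Relative to those levels, the 3 classes held 1.27% to 5.27% in B-ALL and 0.26% to 1.25% in control mice. Expression by the lymphoid cells themselves could not be tested: after subtraction 0.0% of the 23 list calls stayed, but the subtraction took 2.76 times the neutrophil RNA seen.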

How the results depend on the processing

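Clustering without called genes, free RNA subtraction, tag ratios of at least 4, T-like cells without cluster 36 and omission of proliferation genes were chosen after the data were seen, and the other alternatives were planned. Of 203 counts of changed genes under settings that keep all mice, 145 stayed within 1.5 times, and of 1711 values of named genes 1638 kept direction and call, 71 lost the call and 2 reversed: Cxcl9, genes changed, B-ALL against control, classical monocyte-like, bone marrow, with equal cell numbers (4.36), and Ccl3, genes changed, B-ALL against control, T-like, bone marrow, with rebuilt cells (−0.0506). With 1 mouse left out, 434 of 608 named values kept their call and 174 lost it, of which 76 were without CON1, 79 without CON2, 10 without BALL8 and 9 without BALL9. The causes of the changes were not tested. No class of classical monocyte-like cells formed at resolution 0.5, so that setting has no value for it, and blood could not be tested for their genes.

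Without any filter on low counts, more genes were tested, and calls were 1279 in classical monocyte-like cells of marrow, 631 and 748 in non-classical monocyte-like cells of marrow and blood, 690 in neutrophil-like cells of marrow, 815 in T-like cells of marrow, 131 and 795 in NK-like cells of marrow and blood and 222 in mature B-like cells of marrow. The differences between tissues were then 109 (non-classical monocyte-like), 263 (T-like), 361 (NK-like) and 191 (mature B-like). DESeq2 gave 229 and 618 for T-like cells of marrow and blood, 29 and 184 for NK-like, 124 and 1269 for mature B-like, and tissue differences of 70 (non-classical monocyte-like), 92 (NK-like) and 72 (mature B-like). Equal cell numbers, which use fewer cells, gave 436 and 505 for neutrophil-like cells of marrow and blood, 193 for T-like cells of marrow, 236 for NK-like cells of blood and 7 for mature B-like cells of marrow, and tissue differences of 2 (non-classical monocyte-like), 352 (neutrophil-like), 33 (T-like) and 8 (mature B-like).

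A fit on 1 tissue gave 646 for classical monocyte-like cells of marrow, 164 for non-classical monocyte-like cells of blood, 115 for neutrophil-like, 257 for T-like, 12 for NK-like and 104 for mature B-like cells of marrow, and 2558 for pro/pre-B-like cells of B-ALL against control. Free RNA subtraction gave 55 for neutrophil-like, 273 for T-like and 12 for NK-like cells of marrow, 104 for NK-like cells of blood, and tissue differences of 1 (non-classical monocyte-like), 26 (T-like), 37 (NK-like) and 13 (mature B-like); with genes of other cell types left out the first was also 1. Rebuilt cells gave 297 for T-like cells of marrow, tissue differences of 10 (non-classical monocyte-like) and 26 (NK-like), and a progenitor-like share of 0.88 (adjusted p = 0.0828). Resolution 2 gave 712 for classical monocyte-like cells of marrow and tissue differences of 128 (NK-like) and 14 (mature B-like). Without doublets, calls were 62 for classical monocyte-like cells of marrow, and tissue differences 3 (non-classical monocyte-like) and 120 (NK-like).

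Share effects that lost their call were those of progenitor-like cells, at 0.91 in thinned cells (0.0609), 1.07 at resolution 0.5 (0.0516) and 0.96 over all cells (0.111); of classical monocyte-like cells of blood, at 0.96 in thinned cells (0.0609); of non-classical monocyte-like cells of marrow (0.95, 0.111) and NK-like cells of blood (0.79, 0.138) over all cells; of mature B-like cells of marrow without called genes (−1.76, 0.0598); and of the tissue difference of classical monocyte-like cells, at 0.59 without called genes (0.645) and 1.34 at resolution 2 (0.159). The marrow excess of non-classical among monocyte-like cells was 5.47 points without called genes, 6.05 at resolution 2 and 31.5 without doublets, and that of blood 29.0 in thinned cells. List calls fell from 219 to 0 with an estimated correlation (camera; 69 at an unadjusted p under 0.05). With the mouse as a replicate block, tissue differences were 203 (non-classical monocyte-like), 356 (NK-like) and 199 (mature B-like), 1 list call in tissue contrasts was lost and 9 were gained, and the block moved no other count by over 1.5 times.

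With each mouse left out in turn, counts ranged from 0 to 1846 (classical monocyte-like, marrow), 0 to 610 and 2 to 946 (non-classical, marrow and blood), 3 to 2083 and 557 to 1920 (neutrophil-like), 98 to 749 and 734 to 1446 (T-like), 0 to 20 and 12 to 682 (NK-like), 52 to 208 and 755 to 2607 (mature B-like), 86 to 6271 (pro/pre-B-like against control) and 624 to 5246 (blood against marrow). Tissue differences ranged from 0 to 164 (non-classical), 204 to 1602 (neutrophil-like), 21 to 81 (T-like), 1 to 140 (NK-like) and 14 to 117 (mature B-like). Counts of 0 came from edgeR with 1 control mouse left, where genes with an unadjusted p under 0.05 numbered 926 and 1014 (classical, without CON1 and CON2), 1076 and 887 (non-classical, marrow), 635 and 511 (non-classical, tissue difference) and 536 and 664 (NK-like, marrow). Share effects ranged from 3.36 to 3.91 (non-classical, blood), 1.2 to 1.27 (marrow, adjusted p = 0.183 without CON1 and 0.274 without CON2), 1.02 to 1.45 (progenitor-like), −4.13 to −2.16 (mature B-like, marrow), −2.37 to −1.19 (NK/T intermediate), 0.98 to 1.12 (NK-like, blood), −2.32 to −1.60 (T-like, blood) and 1.34 to 2.53 (classical, blood), tissue differences from 2.09 to 2.71 (non-classical) and 2.06 to 3.21 (classical), and calls among the 26 share tests from 1 to 11. The non-classical excess among monocyte-like cells ranged from 24.2 to 30.7 points in marrow and 9.41 to 16.6 in blood.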

Other observations

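The tests in this part were chosen after the results were seen, except the camera tests of the heat shock list, which were planned. The 2 B-ALL mice differed from each other in interferon genes, values that have no test because they compare single mice. In non-classical monocyte-like cells of blood, the median of 14 interferon-γ response genes was 2.10 higher on the log2 scale in BALL9 than in BALL8 (14 of 14 higher), and that of 18 interferon response genes 1.72 (18 of 18). Class I antigen presentation genes (12 of 12, median 1.10) and class II genes (8 of 8, 1.85) went the same way. Classical monocyte-like cells of blood showed 1.98 for the interferon-γ list (18 of 18) and those of marrow 1.34 (17 of 18), and the pro/pre-B-like cells of blood 1.46 (16 of 16). Between CON1 and CON2 the interferon-γ list of non-classical monocyte-like cells of blood differed by −0.11 (CON2 minus CON1). Control mice differed elsewhere: in NK-like cells of marrow by 0.79 for the interferon list (12 of 14) and 0.54 for the interferon-γ list (13 of 14), above 0.14 and 0.42 in the B-ALL pair, and in T-like cells of marrow by 0.59 for the interferon list (22 of 23), against 0.64. T-like and NK-like cells of B-ALL blood differed less, with interferon-γ medians of 0.45 and 0.09.

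Y-linked transcripts in pro/pre-B-like cells of B-ALL mice, which the labels call female, were the second pattern weighed. Clusters led by B-ALL cells held 2111 such cells with 147 CPM over 4 Y-linked genes, and 78.7% of cells had 1 or more such UMIs, against 0 UMIs in the 54 B-ALL cells that lay in clusters led by control cells, at median depths of 13509 and 1935 UMIs. In marrow, Ddx3y, Eif2s3y, Kdm5d and Uty had 1021, 648, 455 and 309 UMIs in B-ALL and 0, 0, 0 and 1 in control pro/pre-B-like cells, which is 0.044% of the B-ALL level and argues against reads of X-linked paralogs. The 13 other combinations of class and tissue of the B-ALL mice with most UMIs reached at most 1.54% of that level, which argues against a male mouse in place of a B-ALL mouse; among smaller ones, NK-like cells of marrow held 4 such UMIs (6.81 CPM) and unnamed cells with low UMI counts 3 (30.3 CPM). In blood, non-classical monocyte-like cells reached 1.2%, which argues against a male origin shared with them. Xist stood at 2.22% of the level of control marrow in the higher B-ALL mouse with blood and marrow pooled, and at 2.40% and 2.48% in marrow alone, so a male donor of the leukaemic cells is a candidate explanation, and loss of Xist for another reason was not tested. Clusters led by B-ALL cells held Xist at 28.5 CPM, and the 54 B-ALL cells without Y-linked UMIs at 1667 CPM.

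Heat shock genes in B-ALL were the third pattern weighed: their list was higher at camera's preset correlation in 11 of 12 comparisons with control, neutrophil-like cells of blood excepted (adjusted p = 0.114), and in 0 with an estimated correlation (2 at an unadjusted p under 0.05). Their list was 0.54 higher in BALL9 than in BALL8 (median of 14 classes and tissues, all 14 above 0), more than the largest difference between control mice of 0.30, so handling of a whole library after pooling does not account for the part that separates the B-ALL mice. Stress during cell preparation stays open, since immediate early genes, which would rise with it, had a median log2 change of −0.14 with an SD of 0.33 over 12 comparisons. Disease stays open too: the lower B-ALL mouse lay above both controls in 11 of 12 classes and tissues, but disease and library cannot be told apart here.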
